A study of Mus musculus with 2 samples.

How the data were processed

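Haematopoietic stem cells (HSCs) had been sorted from mouse fetal liver and adult bone marrow, per the labels' protocol. Polyadenylated RNA was then selected, fragmented to about 300 nt, made into libraries with an NEBNext Ultra RNA kit and sequenced in paired-end mode. The protocol text names read lengths of 100 nt and of 75 nt without saying which libraries each belongs to. The labels list the molecule as genomic DNA, although the protocol describes RNA. The sort markers and the number of mice per library are not given in the sources used here.

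The authors deposited FPKM values (fragments mapped to a feature, scaled by the feature's length and by the library's total of mapped fragments) in 2 tables, 1 for genes and 1 for transcripts, each with a column headed FL and a column headed BM. TopHat, Cufflinks, featureCounts of the Subread package and edgeR, and the mouse build mm9, are named in the submitters' processing notes. The notes carry no role, order or version for these tools, and the annotation release is not given in the sources used here. FPKM divides by feature length and by library total, so a few abundant genes can shift all others in a column. Cufflinks shares reads among overlapping transcripts by a model, so values of isoforms and of near-identical genes are estimates. In the gene table, 66.5% of the non-zero FL values (13798 of 20739) had repeating decimals of the kind that a mean of 3 rounded values leaves, and 0 of the BM values had. No column carries a replicate number. Each was read as the authors' mean over libraries, with no SD, no n and no test between columns. The columns headed BM were assigned, by their header alone, to the adult bone marrow HSC group of the labels, which holds 2 samples. The BM columns of the 2 tables held different values, so this assignment is in doubt for at least 1 of them. The column headed FL was read as fetal liver HSCs from the protocol alone. Counts were not used here, and FPKM does not retain depth, so the depth behind each value is unknown and no interval is given.

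The tables identify features by Ensembl gene and transcript identifiers. Symbols and the link from transcript to gene were taken from the GENCODE annotation of a later mouse build by identifier alone, and no coordinates are printed because the builds differ. A symbol was found for 32819 of 37820 genes, and genes without a symbol carried 1.18% of the FPKM in the FL column and 0.960% in the BM column. A gene was found for 76507 of 87641 transcripts. The unlinked transcripts carried 10.4% of the FPKM in the FL column and 10.9% in the BM column. Transcript FPKM were summed per gene, which gave 28009 genes, 26967 of them also in the gene table. A sum is too low where an abundant transcript was not linked. Pcna had 447 FPKM in the BM column of the gene table and a sum of 13.9 FPKM in the FL column of the transcript table. Whether an unlinked transcript is the cause was not checked for this gene. All calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.

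Fixed before the data were examined were 27 gene lists, 34 gene pairs, 35 genes for isoform usage and the rule for the genes named. The lists cover HSC identity, haematopoietic transcription factors, genome organisation, chromatin and DNA methylation, fetal HSC-associated genes, imprinted genes, quiescence and cell cycle inhibitors, proliferation, Hox genes, MHC class I, MHC class II, interferon response, immediate early and heat shock genes, glycolysis and hypoxia, oxidative phosphorylation, housekeeping and sex-linked genes. Another 10 lists hold markers of erythroid cells, neutrophils and monocytes, macrophages, B cells, T and NK cells, megakaryocytes, mast cells and basophils, endothelium, stroma and hepatocytes. The rule allowed the 10 genes with the highest BM value, the 4 highest members of each list and up to 3 members under 0.1 FPKM, both genes of each pair, the isoform genes, all members of lists of 5 genes or fewer, and the 5 largest and 5 smallest ratios among genes with a mean of 5 FPKM or more. Comparing the BM with the FL column, comparing the tables with each other, and naming list members by the size of their difference were decided after the files were seen. Many of the genes named in those comparisons were therefore chosen after their values were known.

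A gene was called detected at 1 FPKM or more. The relative log2 ratio of a gene was log2((BM + 0.1) / (FL + 0.1)) minus the median of that ratio over genes at 1 FPKM or more in both columns, so it understates the difference of genes near the pseudocount of 0.1. A gene at 1 FPKM or more in either column is called expressed, and expressed genes with a relative ratio of at least 2-fold were counted as higher or lower. The median of each list was ranked among 10000 random lists of the same size, drawn from the 100 genes nearest in mean level to each member; this percentile describes the columns and is not a test. The 2 tables were matched through 2097 genes with a single linked transcript and at least 5 FPKM in all columns, as the share of genes within 10% of the median ratio. In simulated data based on 11405 genes, a scaled copy of a column gave a share of 100%, a permuted column gave 4.03%, and 97% of genes changed 4-fold passed the 2-fold limit in the right direction. These outcomes follow from the simulated noise and shifts, so they check the calculation only. Pairings of the deposited columns that did not match gave shares of 16.6% to 20.8%. The dominant transcript was the one with the highest share of a gene's summed FPKM, for genes with 2 or more transcripts and a sum of 1 FPKM or more.

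Alternatives were other pseudocounts, detection limits and filters, no centring, upper-quartile scaling, list means in place of medians, and the transcript table in place of the gene table. Planned results that need separate libraries were not run on the authors' means: the agreement of replicates, leaving out either replicate, and pair orders judged by standard errors. Symbols not matched in the gene table, and not analysed here at gene level, were Zfpm1, Kcnq1ot1, Cdkn2d, Hoxd4, Psmb9, Cox4i1, Hbb-b1, Hbb-b2 and Ahsp. Jun, Junb, Jund and Cebpa were not analysed here in the transcript table.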

Results

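Gene expression in fetal and adult haematopoietic stem cells (HSCs), the cells that sustain all blood lineages, was profiled by sequencing of polyadenylated RNA, in a study of how the genome is reorganised between these stages. The adult HSCs were sorted from the bone marrow of B6129SF1 mice aged 6 to 8 weeks and are described by 2 samples, replicates 1 and 2. Fetal HSCs came from embryonic liver, per the labels' protocol; separate fetal samples were not analysed here. The values are the authors' mean FPKM in a gene table and in a transcript table, each with a column headed FL (fetal liver) and a column headed BM (bone marrow). Without replicate values no difference below could be set against the spread between libraries, and "higher" and "lower" describe these columns only. The sequencing depth is unknown.

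In the gene table, 13029 of 37820 genes were at 1 FPKM or more in the FL column and 12210 in the BM column. In the transcript table, 24301 of 87641 transcripts reached that level in the FL column and 26469 in the BM column; after summing per gene, 11445 genes did so in FL and 11652 in BM. Genes for protein synthesis were among the most abundant in both tables. In the BM column of the gene table the most abundant were Rpl13a, a ribosomal protein gene, at 9461 FPKM, the mitochondrial ATP synthase gene mt-Atp8 at 6906 FPKM and the elongation factor gene Eef1a1 at 6812 FPKM. In that of the transcript table they were Eef1a1 at 7099 FPKM and the ribosomal protein genes Rps14 at 5197 FPKM and Rplp1 at 4596 FPKM. Genes of ribosomal proteins took 18.3% of all FPKM in the FL column and 23.6% in the BM column of the gene table. In the transcript table they took 23.6% in FL and 24.7% in BM. All 18 mitochondrial genes were listed at 0 in both columns of the transcript table.

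The columns of the 2 tables did not match by their headers. Hmga2, a chromatin protein gene of fetal HSCs, was at 96.5 FPKM in the BM column of the gene table, at 93.0 FPKM in the FL column of the transcript table and at 3.27 FPKM in the BM column of the transcript table. The erythroid factor gene Klf1 was at 87.0, 82.8 and 7.82 FPKM in these columns, and the immediate early gene Fos at 0.477, 0.422 and 158 FPKM. Among 2097 genes with a single linked transcript, 80.3% lay within 10% of a constant ratio between the BM column of the gene table and the FL column of the transcript table, with a median log2 ratio of -0.06 and quartiles of -0.08 and -0.06. That share was 20.8% between the columns headed BM, 17.5% between the columns headed FL, and 16.6% between the FL column of the gene table and the BM column of the transcript table. Pearson's r of log2 values across these genes, which are not independent replicates, was 0.949 for the first pairing, 0.881 for BM with BM, 0.826 for FL with FL and 0.799 for the last. Over all genes at 1 FPKM or more in both tables, the gene values and summed transcripts correlated with r = 0.880 for BM and r = 0.795 for FL. The column headed BM in the gene table thus held, for most genes, the values headed FL in the transcript table. Every value below is given by the table and the header it stands under, and the tables are described separately.

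**Figure D1:**
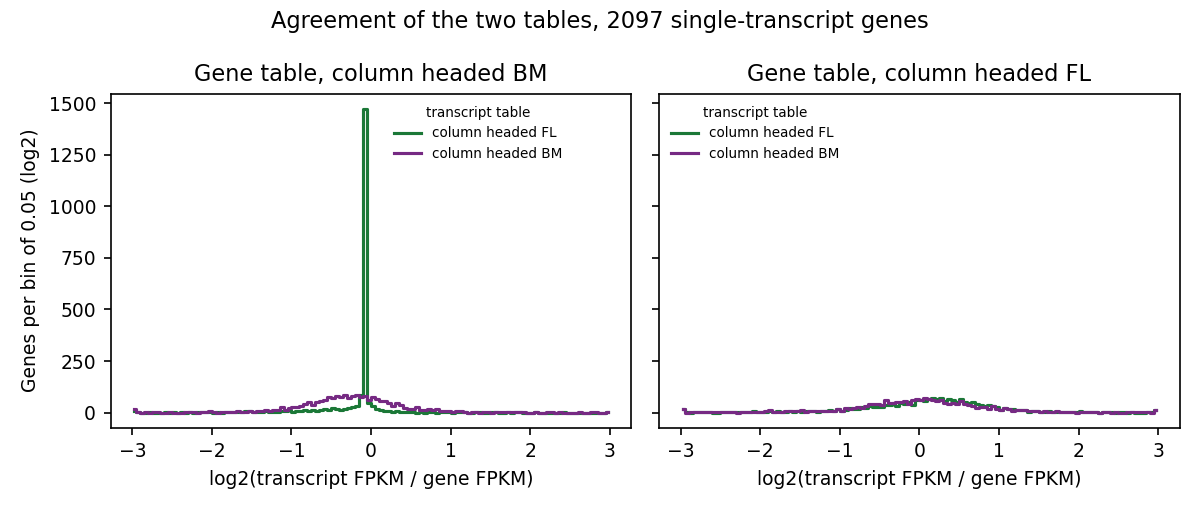
Histograms of the log2 ratio of transcript-table FPKM to gene-table FPKM for 2097 genes with a single linked transcript (x axis, log2, with ratios beyond 3 placed in the outermost bins; y axis, genes per bin). Left, the gene-table column headed BM, whose ratio to the transcript-table FL column (green) forms a narrow peak that holds most genes, while its ratio to the transcript-table BM column (purple) is broad; right, the gene-table FL column, broad against both.

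The transcript table was used first to ask how the column headed BM differs from that headed FL. Genes known from fetal HSCs were far lower in BM. Of the 14 fetal HSC-associated genes, 11 were expressed and 10 were at least 2-fold lower in BM, with a median relative log2 ratio of -5.16, at percentile 0 of 10000 random lists matched on level. Lin28b, an RNA-binding protein gene that sets the fetal programme of HSCs, was at 8.51 FPKM in FL and 0.304 FPKM in BM. Igf2bp1 and Igf2bp3, which encode fetal mRNA-binding proteins, were at 19.6 and 20.1 FPKM in FL against 0.0611 and 0.407 FPKM in BM. The growth factor gene Igf2 was at 53.9 against 1.42 FPKM, and the embryonic globin gene Hbb-y at 24.4 against 0.0813 FPKM. The expressed gene outside this group was Plag1, a growth-related transcription factor gene, at 12.3 FPKM in FL and 16.0 FPKM in BM. Erythroid, neutrophil and monocyte, and macrophage markers were lower in the same column, with medians of -3.74, -2.98 and -5.42. Among all 12220 expressed genes, 1621 were at least 2-fold higher and 1078 at least 2-fold lower in BM, relative to a median gene shifted by 0.01 (log2). The columns correlated with r = 0.915 across 10877 genes.

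**Figure D2:**
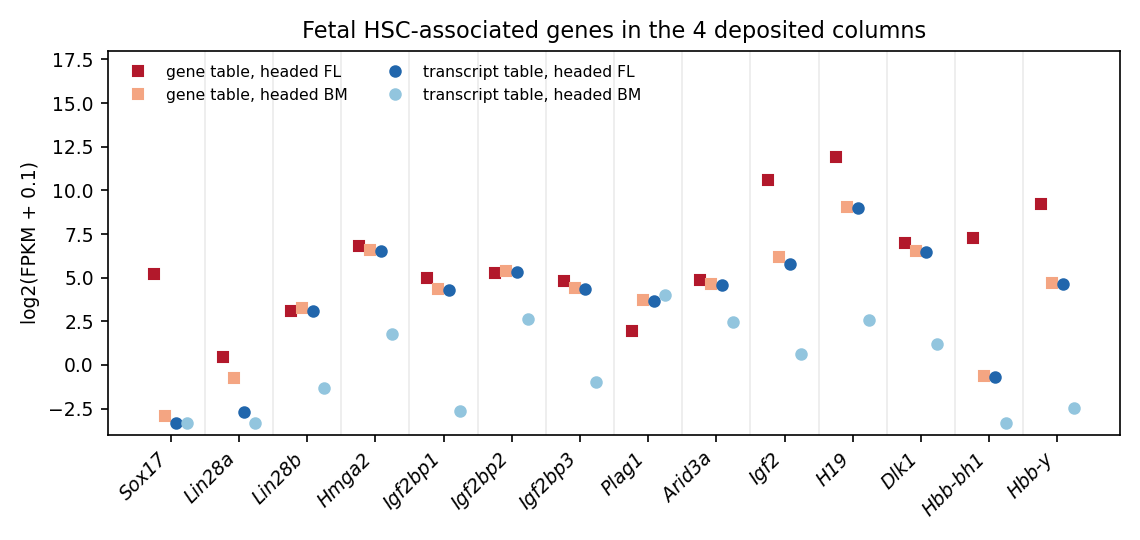
FPKM of the 14 fetal HSC-associated genes (y axis, log2(FPKM + 0.1)) in the 4 deposited columns, each point being the authors' mean. For Hmga2, the gene-table BM column (96.5 FPKM) and the transcript-table FL column (93.0 FPKM) nearly coincide and lie far above the transcript-table BM column (3.27 FPKM), a layout shared by most of the genes.

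Imprinted genes, which are expressed from a single parental allele and often control growth, were mostly lower in BM of the transcript table: 9 of 15 expressed members were lower and 2 were higher, with a median of -1.21 at percentile 0. The non-coding RNA H19 was at 504 FPKM in FL and 5.78 FPKM in BM, and Dlk1, a Notch-related growth regulator gene, at 89.7 and 2.17 FPKM. H19, Dlk1 and Igf2 belong to the fetal HSC-associated list as well and had the lowest ratios (-6.43, -5.31 and -5.16). The results of these lists are therefore not independent. Meg3, a non-coding RNA, and Phlda2, a placental growth regulator gene, were the higher members, at 5.83 and 2.44 FPKM in FL against 14.9 and 8.22 FPKM in BM.

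Markers of differentiated blood cells were lower in BM of the transcript table for the erythroid and myeloid lineages and higher for megakaryocytes. Of 12 expressed erythroid markers 11 were lower (median -3.74), among them Klf1 and the erythropoietin receptor gene Epor, at 46.7 FPKM in FL and 16.0 FPKM in BM; Car1, a carbonic anhydrase gene, was higher, at 16.9 and 44.2 FPKM. The adult globin genes Hbb-bt and Hbb-bs, near-identical copies whose separate values are uncertain, were at 207 and 150 FPKM in FL against 6.04 and 3.75 FPKM in BM. Neutrophil and monocyte markers were lower for 11 of 15 expressed members (median -2.98), with the granule enzyme gene Mpo at 167 FPKM in FL and 9.27 FPKM in BM and the calprotectin subunit gene S100a8 at 107 and 13.6 FPKM. All 10 expressed macrophage markers were lower (median -5.42), including the complement genes C1qa and C1qb at 38.3 and 53.2 FPKM in FL against 1.09 and 1.48 FPKM in BM. The mast cell and basophil list had 3 expressed members, all lower (median -3.34), as were 6 of 7 expressed hepatocyte markers (median -3.76), with the albumin gene Alb at 6.46 FPKM in FL and 0.0190 FPKM in BM. Of 11 expressed megakaryocyte markers 7 were higher and 1 was lower (median 1.98, percentile 100). The platelet chemokine gene Pf4 was at 70.5 FPKM in FL and 535 FPKM in BM, and the integrin gene Itga2b at 22.2 and 149 FPKM.

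Endothelial, stromal and lymphoid markers of the transcript table varied in level. Of 10 expressed endothelial markers 5 were lower in BM and none was higher (median -1.06), with Cdh5, the endothelial cadherin gene, at 7.67 FPKM in FL and 0.0183 FPKM in BM. The stromal list had 3 expressed members, of which the collagen gene Col1a2 (1.67 and 5.74 FPKM) and the growth factor receptor gene Pdgfrb (0.874 and 2.46 FPKM) were higher in BM (median 1.39). Of 4 expressed T and NK cell markers 2 were higher (median 1.44), with the cytotoxic granule gene Nkg7 at 4.31 FPKM in FL and 21.0 FPKM in BM. Of the 2 expressed B cell markers the immunoglobulin gene Ighm was lower, at 2.92 and 0.394 FPKM, and Cd79b was at 18.7 and 16.5 FPKM.

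Antigen presentation genes, and some interferon response genes, were higher in BM of the transcript table. All 8 expressed MHC class II genes were at least 2-fold higher (median 2.22), with the chaperone gene H2-DMa at 6.91 FPKM in FL and 48.2 FPKM in BM and the invariant chain gene Cd74 at 8.88 and 27.2 FPKM. Of 10 MHC class I genes 9 were higher (median 2.01), with B2m, the common light chain gene, at 332 FPKM in FL and 1662 FPKM in BM and H2-K1 at 143 and 905 FPKM; both lists lay at percentile 100. Reads shared among H2 genes make their separate values uncertain. Of 17 expressed interferon response genes 7 were higher, 9 were within 2-fold and 1 was lower (median 0.98, percentile 99.99), with the antiviral membrane protein gene Ifitm3 at 220 FPKM in FL and 471 FPKM in BM. Immediate early and heat shock genes, which respond within minutes to stimulation or stress, were higher for 11 of 16 expressed members with none lower (median 2.26, percentile 100). Fos and Fosb were at 0.422 and 0.0267 FPKM in FL against 158 and 26.5 FPKM in BM, and the phosphatase gene Dusp1 at 8.04 and 105 FPKM.

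Proliferation genes were lower or within 2-fold in BM of the transcript table. Of 26 members 11 were lower and none higher (median -0.84, percentile 0), with the mitotic kinase gene Plk1 at 62.9 FPKM in FL and 14.0 FPKM in BM and the cyclin E gene Ccne1 at 36.9 and 7.43 FPKM. Mki67, a general marker of cycling cells, was at 32.1 and 32.5 FPKM. The erythroid, neutrophil and monocyte, and macrophage markers were lower in the same column, as given above. Among quiescence and cell cycle inhibitor genes, 6 of 18 expressed members were higher and none lower (median 0.49, percentile 99.53), including the inhibitor gene Cdkn2c at 2.24 and 12.4 FPKM and Rbl2, a retinoblastoma family gene, at 9.82 and 27.1 FPKM. Oxidative phosphorylation genes were lower by at least 2-fold for 3 of 23 members (median -0.73, percentile 0), with the ATP synthase gene Atp5b at 2251 FPKM in FL and 1127 FPKM in BM. Glycolysis and hypoxia genes were lower for 4 and higher for 2 of 25 (median -0.43, percentile 3.16). The housekeeping list, which shares Gapdh, Pgk1 and Sdha with these 2 metabolic lists, had a median of -0.41 (percentile 9.49). The glycolysis median is thus not particular to glycolysis genes, and the oxidative phosphorylation median lay only somewhat lower. The glycolytic enzyme gene Eno1 was at 399 and 159 FPKM, and the pyruvate dehydrogenase kinase gene Pdk4 at 0.107 and 1.65 FPKM.

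HSC identity genes were expressed in both columns of the transcript table and 17 of 22 were within 2-fold (median 0.36, percentile 99.88). The higher members were Ly6a, which encodes the Sca-1 antigen, at 6.62 FPKM in FL and 36.0 FPKM in BM, the transcription factor gene Meis1 at 66.8 and 162 FPKM, Pdzk1ip1 at 37.4 and 115 FPKM, and Ptprc, which encodes CD45, at 3.32 and 9.57 FPKM. The Ptprc values rest on 1 linked transcript. The BM column of the gene table, which matches this FL column, had Ptprc at 21.4 FPKM. The ratio may therefore not hold for the whole gene. Cd48, a surface marker of progenitors, was lower, at 25.1 and 6.09 FPKM. Of 25 haematopoietic transcription factor genes 3 were higher, among them Meis1 and Gata2 (68.3 and 165 FPKM), and 3 were lower, Gata1 (51.4 and 24.4 FPKM), Gfi1 (34.2 and 3.37 FPKM) and Ikzf1 (89.4 and 19.8 FPKM), with a median of 0.11.

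Genes of genome organisation, the process the study addresses, were mostly at like levels in both columns of the transcript table. Of 36 genes 31 were within 2-fold, with a median of -0.02 that was 0.09 under upper-quartile scaling without centring. Ctcf, whose protein binds loop anchors and domain boundaries, was at 70.3 FPKM in FL and 72.4 FPKM in BM. The cohesin genes Rad21 (81.2 and 67.4 FPKM), Smc1a (80.5 and 116 FPKM) and Smc3 (39.5 and 54.4 FPKM) were within 2-fold. The members at least 2-fold lower were the condensin genes Ncaph (36.4 and 8.27 FPKM) and Ncapd2 (68.7 and 34.0 FPKM), the lamin gene Lmna (30.2 and 8.79 FPKM) and the chromatin organiser gene Satb1 (8.06 and 2.05 FPKM). The cohesin acetyltransferase gene Esco1 was higher, at 3.47 and 8.03 FPKM. Of 33 expressed chromatin and DNA methylation genes 4 were higher and 4 lower, with a median of -0.10 that was 0.01 under upper-quartile scaling without centring. The DNA methyltransferase genes Dnmt3a (72.9 and 30.9 FPKM) and Dnmt3b (96.8 and 35.6 FPKM) were lower, and the Polycomb gene Cbx7 (7.76 and 20.3 FPKM) and the remodeller gene Smarca2 (16.5 and 50.6 FPKM) higher. The BM column of the gene table, which matches this FL column, had Smarca2 at 39.9 FPKM. The Smarca2 ratio may therefore not hold for the whole gene.

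The same question was then put to the gene table, where 39.6% of 2522 genes at least 2-fold apart, among genes at 1 FPKM or more in all columns, had the same sign in the transcript table. Its BM column matches the FL column of the transcript table, so these values enter the ratios of the 2 tables on opposite sides, and opposite directions are partly built in. The BM column of the gene table may therefore not describe adult HSCs. Endothelial and stromal genes were far lower in its BM column. All 11 endothelial markers were lower (median -5.45, percentile 0), with Plvap, a protein gene of fenestrated endothelium, at 599 FPKM in FL and 7.54 FPKM in BM, Cdh5 at 457 and 7.97 FPKM and the VEGF receptor gene Kdr at 214 and 1.83 FPKM. All 10 expressed stromal markers were lower (median -5.81, percentile 0), with the matrix gene Sparc at 478 and 8.08 FPKM and the collagen gene Col3a1 at 87.4 and 0.109 FPKM. The fetal HSC-associated, imprinted, quiescence, Hox and immediate early lists were lower in the same column as these markers. Among 13834 expressed genes 1708 were higher and 3270 lower in BM, relative to a median gene shifted by 0.24 (log2); without that centring 2376 were higher and 2826 lower. The columns correlated with r = 0.831 across 11405 genes.

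**Figure D3:**
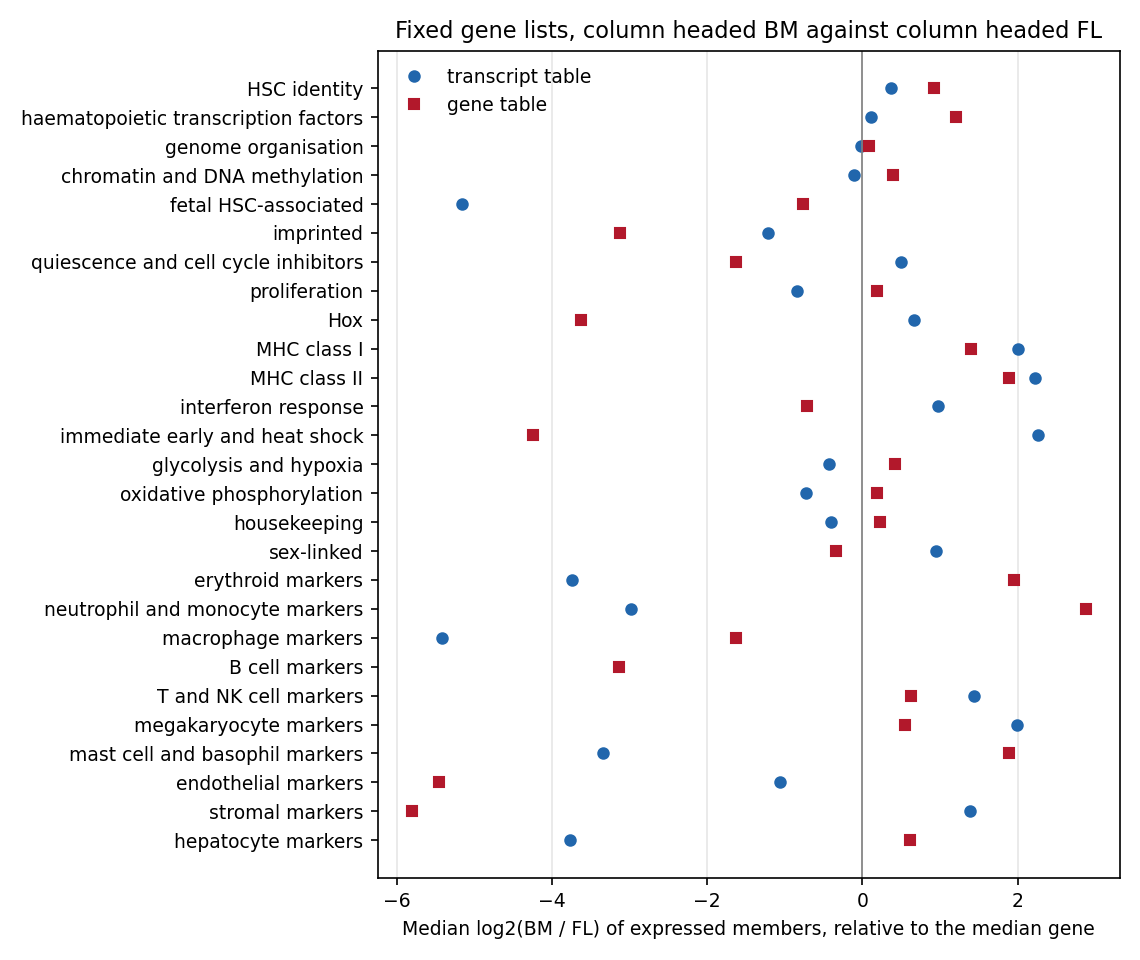
Median log2 ratio of BM to FL over the expressed members of each fixed list, relative to the median gene (x axis, log2), in the transcript table (blue circles) and the gene table (red squares); lists with under 3 expressed members in a table have no point. Fetal HSC-associated genes had medians of -5.16 and -0.77, and immediate early and heat shock genes lay on opposite sides of 0, at 2.26 and -4.24.

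Of the fetal HSC-associated genes of the gene table, 14 were at 1 FPKM or more in FL and 11 in BM. Of 14 expressed members 6 were lower and 1 was higher in BM (median -0.77, percentile 0.540). Lin28b was at 8.33 FPKM in FL and 9.65 FPKM in BM, Hmga2 at 111 and 96.5 FPKM and Igf2bp3 at 28.1 and 20.8 FPKM. The lower members included Sox17, a transcription factor gene of fetal HSCs and of endothelium, at 37.1 and 0.0335 FPKM, the embryonic globin gene Hbb-bh1 at 152 and 0.544 FPKM and Igf2 at 1546 and 72.8 FPKM. Imprinted genes were lower for 15 of 17 members and higher for none (median -3.12, percentile 0), with H19 at 3859 and 525 FPKM and the growth-related gene Mest at 1559 and 7.53 FPKM.

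Many haematopoietic genes were higher in BM of the gene table. Of 26 transcription factor genes 17 were higher and 1, Ets1, was lower (median 1.21, percentile 100), with Gata1 at 0.906 FPKM in FL and 53.7 FPKM in BM, Ikzf1 at 13.9 and 151 FPKM and Myb, a regulator gene of progenitors, at 17.8 and 123 FPKM. Of 22 HSC identity genes 11 were higher and 7 lower (median 0.92, percentile 99.99). The SLAM receptor gene Slamf1 was at 0.652 and 14.9 FPKM. The lower members included Vwf, Tek and Esam, which endothelial cells also express, at 174, 105 and 175 FPKM in FL against 13.5, 12.4 and 44.4 FPKM in BM. Erythroid markers were higher for 8 of 12 members and lower for 1 (median 1.95, percentile 100), and neutrophil and monocyte markers for 10 of 15 with 2 lower (median 2.88, percentile 100), with Mpo at 20.1 and 175 FPKM and Elane, a neutrophil protease gene, at 0.0964 and 46.3 FPKM. Of 4 expressed mast cell and basophil markers 3 were higher (median 1.88). Macrophage markers were lower for 6 and higher for 3 of 10 (median -1.64, percentile 0.05), with C1qb at 206 and 55.8 FPKM and the scavenger receptor gene Marco at 0.372 and 28.4 FPKM.

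The remaining cell type markers of the gene table went both ways. Of 11 expressed megakaryocyte markers 4 were higher and 3 lower in BM (median 0.55). Pf4 was among the lower, at 147 and 74.9 FPKM. Of 4 expressed T and NK cell markers 2 were higher and 1 lower (median 0.62), and of 3 expressed B cell markers 2 were lower and none higher (median -3.13). Of 7 expressed hepatocyte markers 3 were higher and 1 lower (median 0.61, and -0.07 over members at 5 FPKM or more), with Alb at 0.381 and 6.74 FPKM.

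Immediate early genes of the gene table were lower in BM, which holds the low values of the transcript table's FL column: 19 of 21 immediate early and heat shock genes were lower and none was higher (median -4.24, percentile 0), with Fos at 138 FPKM in FL and 0.477 FPKM in BM and Jun at 161 and 6.65 FPKM. Quiescence and cell cycle inhibitor genes were lower for 9 of 17 expressed members and higher for 1 (median -1.62, percentile 0), with the inhibitor gene Cdkn1c at 240 and 36.2 FPKM; Foxo3, a stress-response factor gene, was higher, at 11.2 and 39.2 FPKM. Interferon response genes were lower for 6 and higher for 1 of 18 (median -0.71, percentile 1.25). MHC class I genes were higher for 5 of 8 expressed members (median 1.40, percentile 100) and MHC class II genes for 8 of 8 (median 1.89, percentile 99.87), the same direction as in the transcript table. The shared column is the higher side here and the lower side there, so neither table repeats the comparison of the other. H2-K1 was at 46.2 and 149 FPKM, while B2m was at 367 and 349 FPKM.

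Cell cycle, energy metabolism and genome organisation genes were mostly within 2-fold in the gene table. This held for 23 of 26 proliferation genes (median 0.18), 22 of 23 oxidative phosphorylation genes (median 0.18), 15 of 24 glycolysis and hypoxia genes (median 0.42), 34 of 36 genome organisation genes (median 0.08) and 28 of 33 chromatin and DNA methylation genes (median 0.39). Mki67 was at 25.7 FPKM in FL and 33.5 FPKM in BM, Ctcf at 46.3 and 72.5 FPKM. The exceptions in genome organisation were Satb1, higher at 4.72 and 12.5 FPKM, and Smchd1, a chromosome-associated protein gene, lower at 21.0 and 6.94 FPKM. The glycolytic genes Ldha (727 and 1768 FPKM) and Hk1 (27.6 and 184 FPKM) were higher. Ldha summed to 797 FPKM in the FL column of the transcript table, which matches this BM column, so its difference is uncertain.

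The levels of other cell types' markers were then set against those of HSC identity genes within each column, to describe what the sorted fractions held. In the BM column of the transcript table all 22 HSC identity genes were at 1 FPKM or more, with a median of 36.7 FPKM, and the list's median log2 level exceeded that of each of the 10 other lists. The smallest differences were 0.97 for megakaryocyte markers, 3.72 for erythroid markers, 4.42 for endothelial markers and 4.60 for neutrophil and monocyte markers. In the BM column of the gene table all 22 were also at 1 FPKM or more, with a median of 39.0 FPKM, and the smallest differences were 0.65 for erythroid markers, 1.05 for neutrophil and monocyte markers and 1.30 for macrophage markers. In the FL column of the transcript table the difference was -0.55 for erythroid markers and 0.89 for neutrophil and monocyte markers. In the FL column of the gene table HSC identity genes had a median of 12.1 FPKM and lay below endothelial markers by a difference of -4.47, macrophage markers by -1.41 and stromal markers by -0.29. Under 0.1 FPKM in both BM columns were the T cell receptor complex gene Cd3g, the T cell gene Cd3e and the B cell gene Ms4a1, the last listed at 0 in both.

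Levels of related genes were compared within the BM columns, since FPKM corrects for length. The first gene of a pair was the higher in 21 of 34 pairs in the gene table and in 23 of 34 in the transcript table; at least a 2-fold difference was reached by the first gene in 15 and 19 pairs and by the second in 6 and 5. In the FL columns the first was the higher in 20 and 21 pairs. Both BM columns had more Stag2 than Stag1, alternative cohesin subunit genes, with log2 ratios of 1.48 in the gene table and 1.47 in the transcript table. Both had more of the B-type lamin gene Lmnb1 than of the A-type gene Lmna (2.84 and 3.77), more Ezh2 than Ezh1, alternative Polycomb methyltransferase genes (2.88 and 1.72), more Foxo3 than Foxo1 (3.42 and 3.22), more Hk1 than Hk2 (3.10 and 3.14), and less Cdk6 than Cdk4, alternative G1 kinase genes (-5.12 and -3.32). The FL columns had the same orders, apart from Foxo3 against Foxo1 in the gene table (-0.40). These orders are thus not particular to the BM columns. The BM columns differed in order for Slamf1 against Cd48, surface markers used to separate HSCs from progenitors (-0.81 and 1.03), for Cdkn1c against Cdkn1b, inhibitors of cyclin-dependent kinases (1.0 and -0.43), for Cbx7 against Cbx2, alternative Polycomb subunits (-0.76 and 1.62), for Rbl2 against Rbl1 (-0.89 and 0.25), for Ccnd2 against Ccnd3 (-0.86 and 0.07) and for Arid1a against Arid1b (0.61 and -0.20). In the FL column of the transcript table, which matches the BM column of the gene table, 0 of the 34 pairs had another order than in that column; Slamf1 against Cd48 was at -1.59, Cbx7 against Cbx2 at -0.77 and Arid1a against Arid1b at 1.25. Gfi1b exceeded Gfi1, related repressor genes, by 0.74 in the gene table and 4.93 in the transcript table, and Gata2 exceeded Gata1 by 0.41 and 2.75.

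Isoform usage was described in the transcript table, as shares of the summed FPKM of a gene's linked transcripts. For Runx1, a transcription factor gene needed for HSC formation, the same linked transcript was highest in both columns. It held 85.6% of the linked FPKM in FL and 99.1% in BM. The linked Runx1 transcripts summed to 19.98 FPKM in FL, against 43.5 FPKM in the matching BM column of the gene table. These shares may therefore not hold for the whole gene, and whether an unlinked transcript is the cause was not checked. Of the 35 genes fixed for this question 28 had 2 or more transcripts, and 22 of these had the same highest transcript in both columns, among them the topoisomerase gene Top2b, whose highest transcript held 97.2% in FL and 92.9% in BM, Foxo3, at 78.2% and 84.9%, and the myeloid factor gene Spi1, at 64.7% and 72.8%. It differed for 6, among them Ikzf1, Meis1, Etv6, Dnmt3a and Ldb1. Ikzf1-206 held 62.2% of the linked Ikzf1 FPKM in FL, and Ikzf1-204 held 40.1% in BM. The Ikzf1 sum in FL was 89.4 FPKM, against 151 FPKM in the gene table's BM column, so the same limit applies. These 2 columns were close for Dnmt3a (72.9 and 72.1 FPKM) and Foxo3 (37.7 and 39.2 FPKM). Dnmt3a-205 held 54.3% of Dnmt3a in FL, and Dnmt3a-218 held 28.0% in BM. Over 7762 genes in BM the highest transcript held a median of 70.8% of a gene's FPKM, and 38.8% of genes had a share of 80% or more; over 7641 genes in FL the median was 72.0%. Of 7332 genes measured in both columns 86.3% had the same highest transcript. The other 1004 had a median highest share of 45.7% in BM, against 75.5% for the rest, and 69 of them had a share of 60% or more in each column. These shares are model estimates without replicates, so differences between columns have no error.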

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

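All comparisons of BM with FL, and their alternatives, and the use of the transcript table's FL column, were added after the data were seen; the other alternatives here were planned. Of 574 alternative values 470 moved little. These include 44 differences within a column under upper-quartile scaling, which multiplies the whole column and can hardly alter them. Of all 574 values, 26 changed sign, 8 of them from a reported difference of at least 2-fold. Among 258 list medians recomputed within a table under other pseudocounts, filters and scalings, 236 stayed within 1.5-fold, 22 moved by more and none that was past 2-fold changed sign. The 3 others that did were hepatocyte markers in the gene table, and genome organisation and chromatin and DNA methylation genes in the transcript table. The 258 include 53 medians without centring and 53 under upper-quartile scaling without centring. Both settings shift all lists of a table by about the same amount. Without centring it was 0.24 in the gene table and 0.01 in the transcript table (log2), within 1.5-fold by construction. These values therefore say little about robustness. Genes detected in the gene table's BM column numbered between 9250 and 13287 against 12210 as reported.

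Taking the transcript table for the gene table under the same headers changed the libraries as well as the quantification. It moved the median difference between HSC identity and other cell type lists in BM from 3.65 to 7.09. It turned the order of 6 pairs, of which Cdkn1c and Cdkn1b, at -0.43, had been at least 2-fold apart. Of 26 list medians 16 changed sign. The 7 of these that had been past 2-fold were quiescence and cell cycle inhibitors (now 0.49), Hox (0.67), immediate early and heat shock (2.26), erythroid (-3.74), neutrophil and monocyte (-2.98), mast cell and basophil (-3.34) and stromal markers (1.39). Opposite signs are partly built in, since the shared column changes sides. Which members count as expressed was also decided within each table, so the medians can cover different genes. Stromal medians rested on 10 expressed members in the gene table but on only 3 in the transcript table, and Hox medians on 31 and 13. For these lists the change of sign therefore does not compare the same genes. The genes lower in BM went from 3270 to 1078. With the transcript table's FL column, which matches the gene table's BM column, the median difference was 3.36, 0 of 34 pairs changed order, and of the 10 other lists the erythroid difference changed sign, from 0.65 to -0.55; the cause of that was not tested. Requiring 5 FPKM in either column, which leaves fewer genes, gave 2018 genes lower in the gene table, and 883 higher and 616 lower in the transcript table.

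No paired analysis was possible because the columns carry no replicate numbers. Leaving out either replicate, the agreement of replicates and pair orders at 2 or 3 standard errors were not run, since the authors' means hold no separate libraries. The depth is unknown, so the precision of low values could not be stated.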

Other observations

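All tests in this part were chosen after the values were seen. Hox genes, which encode positional transcription factors, were lower in the BM column of the gene table for 24 of 31 expressed members and higher for none (median -3.63, percentile 0.03). Stromal and endothelial markers were lower in the same column, with medians of -5.81 and -5.45. In the C and D clusters 12 of 17 genes were at 1 FPKM or more in its FL column and none in its BM column. Hoxd8 was at 14.2 FPKM in FL and listed at 0 in BM, whereas Hoxa9, the most abundant Hox gene of the BM columns, was at 45.3 and 63.7 FPKM. Of 13 expressed Hox genes of the transcript table, 2 were higher in BM and none was lower (median 0.67), with Hoxa9 at 58.8 FPKM in FL and 51.7 FPKM in BM. All 15 housekeeping genes of the transcript table were within 2-fold (median -0.41), as were 13 of 15 in the gene table (median 0.22). Of the 5 sex-linked genes all were within 2-fold in the gene table (median -0.34), and Xist (23.9 and 54.4 FPKM) and Eif2s3y (15.5 and 31.5 FPKM) were higher in BM of the transcript table (median 0.95). Each of the 4 columns held both Xist and the Y-linked genes at 1 FPKM or more.

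Among genes with a mean of 5 FPKM or more, the 10 lowest ratios of BM to FL in the gene table included 7 genes of small RNA classes and the 10 highest included 8; in the transcript table these numbers were 9 and 7. The protein-coding genes with the highest ratios in the transcript table were Fos and the MHC class I gene H2-Q6, at 0.457 FPKM in FL and 150 FPKM in BM.

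The BM column of the gene table matched the FL column of the transcript table. Different processing of the same libraries under correct headers is argued against by the share of genes within 10% of a constant ratio, 20.8% between the columns headed BM. Exchanged headers in the transcript table are argued against by the fetal HSC-associated genes, of which 0 were at least 2-fold higher in its BM column. A wrong header in the gene table remains open and may account for the match: the shared column carries the fetal genes in the transcript table, with a median of -5.16 for BM against FL. The 14 fetal HSC-associated genes had a median of 22.7 FPKM in the gene table's BM column. Their median was 21.9 FPKM in FL and 0.912 FPKM in BM of the transcript table. Comparisons of BM with FL in the gene table may therefore not set adult against fetal HSCs. An exchange of both gene-table headers would need its FL column to match the transcript table's BM column, and that share was 16.6%; the reading also relies on what is known of the fetal genes, not on library records.

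Endothelial and stromal genes were high in the FL column of the gene table, led by Plvap at 599 FPKM, Cdh5 at 457 FPKM and Emcn at 446 FPKM. A lower share of HSCs with more of every other cell type is argued against, since the endothelial and the neutrophil and monocyte lists moved apart by 8.33 (log2). A difference between fetal and adult HSCs is argued against as the whole cause: across separately normalised tables, the 21 expressed markers were a median of 5.26 (log2) higher there than in the higher transcript-table column, with Plvap at 7.21 and 0.634 FPKM in those columns. Endothelial cells in the libraries, by admixture or by the sorting gate, were not tested apart from the pattern itself: that 11 of 11 endothelial markers were at least 2-fold higher in FL restates it, the stromal genes are not covered, 6 of the 11 were also at 1 FPKM or more in BM of the transcript table, and the sort markers are not given in the sources used here. The columns headed FL did not hold the same values, with 17.5% of genes within 10% of a constant ratio. The transcript table's FL column matched the gene table's BM column instead, at 80.3%. Whether libraries of another cell preparation account for the endothelial and stromal genes remains open.

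Immediate early genes were low in the 2 columns that match, with Fos at 0.477 FPKM in BM of the gene table and 0.422 FPKM in FL of the transcript table, and high in the other columns, at 138 and 158 FPKM. The tables had opposite directions, with 19 members lower in BM of the gene table and 11 higher in BM of the transcript table. This follows in part from the shared column, which stands on opposite sides of the ratios. These counts are the pattern itself and give no evidence for or against handling of the cells before lysis. Each column is a single mean, so handling and cell type cannot be told apart. A biological difference between fetal and adult HSCs could not be judged from the gene table. In its FL column HSC identity genes lay below endothelial markers by a difference of -4.47 (log2). That column may therefore not describe fetal HSCs alone. The median of the immediate early and heat shock list was 68.3 FPKM in the gene table's FL column. It was 2.49 FPKM in the transcript table's FL column, and 3.09 and 24.3 FPKM in the BM columns. Both gene-table columns also carried the fetal HSC-associated genes, with medians of 38.1 FPKM in FL and 22.7 FPKM in BM. For the transcript table alone such a difference remains open and untested.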
